A study of Mus musculus with 2 samples.

How the data were processed

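Droplet-based 3′ single-cell RNA sequencing was made of 2 livers of chimaeric mice, 1 labelled E18.5 and 1 labelled P180, with 10x Chromium 3′ v3 chemistry on an Illumina NovaSeq, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 per the file headers and tested here to be whole numbers. The submitters' processing notes name fastp, Trimmomatic, Cell Ranger, Seurat, edgeR and the genome mm10 without a role or version. Which reads were removed, and how barcodes were called as cells, is not given in the sources used here. The lowest barcode total is 500 UMIs in both libraries. The gene table holds 0 tdTomato features, so every comparison of tdTomato-positive cells was left out, and the labels' statement on these cells is not analysed here.

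Barcodes were kept with at least 200 genes, at least 500 UMIs and under 25% of UMIs from mitochondrially encoded genes. Doublets were scored with Scrublet (scanpy 1.11.5), and in each library the barcodes with the highest scores were left out at a rate of 0.8% per 1000 barcodes kept, which removed 178 barcodes (3.77%) with the E18.5 label and 735 (7.67%) with the P180 label. Scrublet's own threshold would have removed 79 and 0 barcodes, so it did not separate doublets in the second library. Each library was clustered on its own. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes were standardised with values clipped at 10, and 30 principal components and 15 nearest neighbours were used (scikit-learn 1.9.0). Leiden clustering followed at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, 5 iterations), with seed 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used on a single thread.

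Clusters were named from 17 marker sets fixed before the data were examined, as were the filters, the gene lists, the statistics and the main alternatives. The exact rule for naming was set after clusters had been seen. A cluster takes the class with the most markers among its 50 genes of highest fold over the 25th percentile of the library's clusters, after adding 10 CPM, for genes found in at least 10% of its cells and with at least 10 UMIs. A cluster with under 3 such markers, or with a tie, stays unnamed. This gave 23 and 21 clusters, and classes are named with the suffix -like since they rest on transcripts alone. In simulated data with 1800 cells of 9 classes, built from the library labelled E18.5, 98.7% of cells received their own class and 0% another (adjusted Rand index 0.987). With 1000 cells of 5 classes, built from that labelled P180, 98.6% received their own and 1.4% another (index 0.925). The simulated cells were drawn from the summed counts of the larger classes found here. High recovery therefore follows largely from the design, and says nothing on whether the classes or names are right. Erythroid-like cells labelled E18.5 and dendritic-like cells labelled P180 were not among the simulated classes.

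With 1 library per stage, cells are not replicates, so no test between stages, p-value or count of changed genes was made. Levels are the UMIs of a gene summed over a class and scaled to a common total (CPM), with exact Poisson 95% intervals. Shares of cells have exact binomial intervals, and ratios the exact conditional interval of a pair of Poisson counts. Where 1 side has a count of 0, the ratio is a lower bound against 3 counts over the class, written as at least that fold. The limit of the exact 95% interval lies lower, at 1045-fold in place of 1285-fold for Xist in B cell-like cells. Classes with at least 50 cells in both libraries were compared, which were 6. Mesenchymal-like cells stayed under this number in the library labelled P180, and no cluster of hepatocyte-, cholangiocyte- or macrophage-like cells was present in both libraries, so these classes and zonation were not compared. A gene list is described by its members with at least 50 UMIs in at least 1 library, the number at least 2-fold higher or lower, the median log2 ratio (for 3 or more members), and the percentile of this median among 10000 random lists matched on expression. Fewer UMIs were summed under the P180 label in B cell-, dendritic- and endothelial-like cells. There, a member that reaches 50 UMIs under that label alone is at least 2-fold higher by construction. The same holds in monocyte-like cells for a member with 0 UMIs under the E18.5 label. The random lists were drawn from genes that met the same minimum. The lists for sinusoids, for capillaries and large vessels, for endothelial proliferation and angiogenesis, and for globins were fixed for the classes they are shown in. The lists of fetal, proliferation, cytokinesis and ploidy, centrosome and spindle, p53, haemoglobin and erythroid, dissociation stress and mitochondrial genes had been fixed for hepatocytes, and that of antigen presentation and inflammation for macrophages; these were applied to the other classes after the clusters had been seen, as was the hepatocyte list of plasma proteins and coagulation. Further lists fixed for absent classes were computed in the 6 classes too but are not reported. For Hhex in bile duct and T cells and for the sex-linked transcripts, cells were also thinned to 1000 UMIs.

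The ratios were tested on simulated data, with 200 genes changed in each of 20 draws, over 5983 genes in B cell-like, 4640 in dendritic-like, 2611 in endothelial-like, 576 in erythroid-like, 4579 in monocyte-like and 3099 in neutrophil-like cells. For a 2-fold change, the share of intervals that held the true ratio was 96.2%, 96.35%, 95.5%, 96.2%, 95.9% and 95.05%, in that order, and the direction was recovered in 100% of cases, or 96.6% in erythroid-like cells. For a 4-fold change the shares were 95%, 96.4%, 95.35%, 95.6%, 95.4% and 95.3%, with every direction recovered. In the first draw of each class, a list of raised genes lay at percentiles 99.96 to 100, and a list of unchanged genes at 12.4 to 97.7. The simulated counts were Poisson draws, which the intervals assume. These shares thus check the calculation only, not how the intervals hold where UMIs are spread unevenly over cells. Summed UMIs set the precision, which is lowest in erythroid-like cells labelled E18.5, with 82 cells.

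Genes to be named were fixed by a rule: Hhex in every class; from each list up to 4 members of largest absolute log2 ratio that keep their direction under every scaling; in each compared class the 4 genes of highest and the 4 of lowest ratio, with at least 200 UMIs in at least 1 library, neither mitochondrial nor a marker of another class, and at least as high in the class as in its whole library; and the genes used to name classes. Members of the lists first fixed for hepatocytes, and Kdr, Flt1, Ighd, Rag1, Dntt, Lin28b, Il1b, Cxcr2, Alb, H2-K1, H2-D1, B2m, Nlrc5 and Cd274, fall outside this rule where they are named and were chosen after their values were seen. The alternatives tried were a mitochondrial limit of 10% or none, at least 1000 UMIs, no doublets left out or Scrublet's own threshold, resolutions of 0.5 and 2, and both libraries clustered together without integration. For ratios they were scaling by the median of ratios over genes with at least 10 UMIs on both sides, totals without haemoglobin and mitochondrial genes, totals without the 50 most abundant genes, the mean of CPM per cell, and list minimums of 10 and 200 UMIs. Alternatives chosen after seeing the data were the Stab2-led endothelial cluster alone, monocyte-like cells without those carrying an Alb UMI, erythroid-like cells without those carrying a B cell marker, and barcodes rich in haemoglobin without a minimum of genes.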

Results

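Single-cell transcriptomes of 2 mouse livers were measured by droplet-based 3′ sequencing of RNA from dissociated cells. Each liver grew in a host in which Hhex had been knocked out and which had received tetraploid (4N) embryonic stem cells at the blastocyst stage, per the labels' protocols. The donor stem cells carried tdTomato, a red fluorescent protein. There was 1 library labelled E18.5 (embryonic, in days after conception) and 1 labelled P180 (postnatal, in days after birth), so neither stage has a replicate and no test between stages was made. The labels give the cell types present and the distribution of tdTomato-positive cells as the purpose. The gene table used here holds 0 tdTomato features, so the tdTomato-positive cells were not analysed here.

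The library labelled E18.5 held 9871 barcodes with 37709972 UMIs (unique molecular identifiers, which count RNA molecules) and 23046 detected genes. For the library labelled P180 these numbers were 9771 barcodes, 90128038 UMIs and 22878 genes. Median UMIs per barcode were 2326 and 5899, in that order, and median genes 684 and 827. Mitochondrial transcripts made up a median 16.7% of a barcode's UMIs with the E18.5 label and 0.655% with the P180 label. The quality filters kept 4721 barcodes (47.8%) and 9582 barcodes (98.1%). After removal of likely doublets, 4543 and 8847 cells remained. All intervals below are 95% intervals (exact Poisson for levels, exact binomial for shares of cells) and cover counting error only, not the difference between animals. Those of levels and ratios treat each UMI as independent, so they also leave out the spread between cells. Paired levels and shares give the library labelled E18.5 first, then that labelled P180.

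Hhex, a homeobox transcription factor needed for the formation of the liver and bile ducts, was detected in both libraries. Its level was highest in bile duct cells (cholangiocyte-like) with the E18.5 label, at 503 CPM (UMIs of a gene scaled to a common total of UMIs; interval 475 to 532). There, 135 of 151 cells (89.4%) carried an Hhex UMI, against 2.11% of T cell-like cells, whose level was 3.86 CPM, at median depths of 11349 and 5241 UMIs. With every cell thinned to 1000 UMIs, these shares were 33.8% and 0.637%. Endothelial-like cells held 132 CPM (121 to 144) in the library labelled E18.5 and 57.7 CPM (40.4 to 79.9) in the library labelled P180. Neutrophil-like cells stood the other way round, with 47.0 CPM (36.2 to 60.0) under the E18.5 label and 111 CPM (107 to 116) under the P180 label.

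Among the other classes, Hhex in B cell-like cells was 75.9 CPM (69.4 to 83.0) with the E18.5 label and 73.1 CPM (62.6 to 84.8) with the P180 label. Monocyte-like cells had 79.5 CPM (65.6 to 95.5) and 99.1 CPM (92.1 to 107), and dendritic-like cells 53.7 CPM (46.8 to 61.4) and 80.7 CPM (67.5 to 95.7), in the same order. Erythroid-like cells held 23.7 CPM (11.4 to 43.6, from 10 UMIs) and 0.882 CPM (0.624 to 1.21, from 38 UMIs). A UMI of a B cell marker was found in 33 of these 82 cells labelled E18.5 and 189 of 6909 labelled P180. Whether their Hhex UMIs come from B cells was not tested. Mesenchymal-like cells had 12 CPM (3.89 to 28.0, 5 UMIs) and 4.67 CPM (0.566 to 16.9, 2 UMIs). In classes named under the E18.5 label alone, Hhex was 73.5 CPM in macrophage-like, 44.8 CPM in NK cell-like and 10.5 CPM in plasma cell-like cells. Clusters without a name held 32.7 CPM under the E18.5 label and 10.3 CPM under the P180 label. Over all cells kept, the level was 99.1 CPM (95.5 to 103) with the E18.5 label and 42.7 CPM (41.3 to 44.1) with the P180 label. Hhex (ENSMUSG00000024986) spans 37434810 to 37440731 on the plus strand of mm10 chromosome 19, with 4 exons in GENCODE mouse release 21. The labels do not state which part was deleted, the origin of cells from host or donor was not measured here, and a 3′ tag outside the deleted part checks nothing about the knockout.

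**Figure D1:**
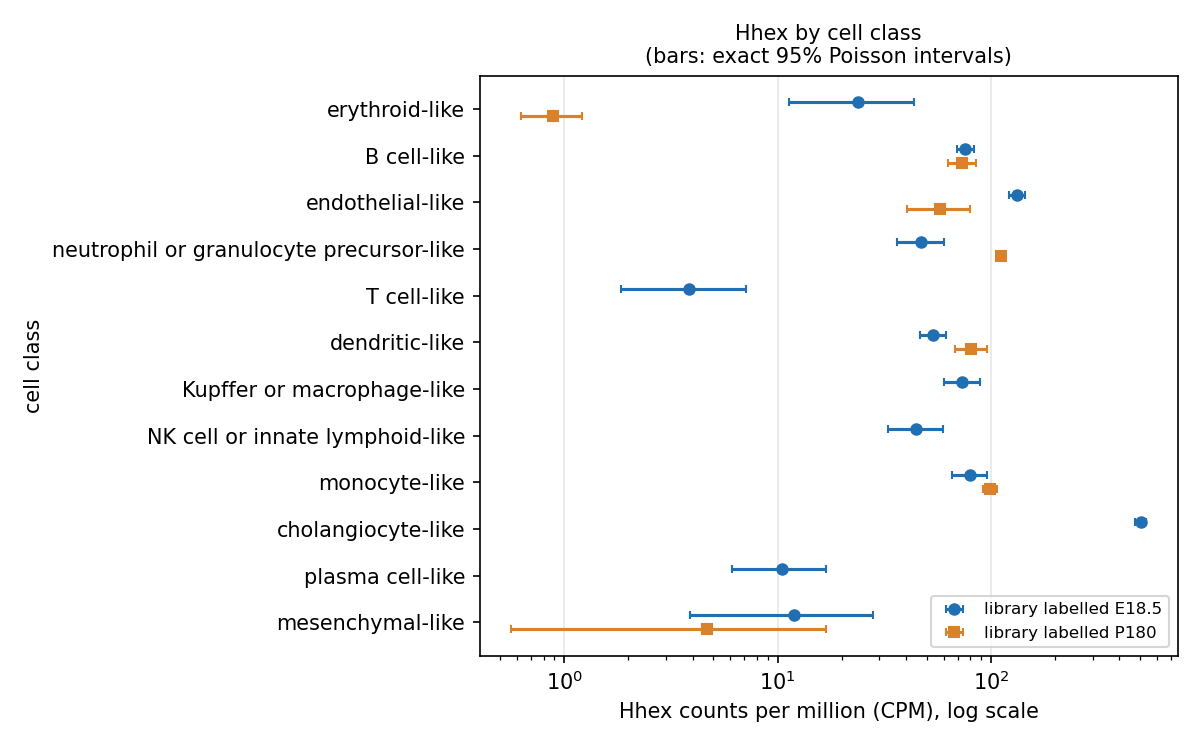
Hhex level by cell class, in CPM of summed UMIs on a log axis, for the libraries labelled E18.5 and P180 (1 library each); points are levels and bars exact Poisson 95% intervals. The highest level is 503 CPM in cholangiocyte-like cells with the E18.5 label, and the lowest 0.882 CPM in erythroid-like cells with the P180 label.

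The makeup of the cells differed widely between the libraries. Mature lymphocytes and endothelial cells led in the library labelled E18.5, where B cell-like cells made up 28.8% (27.5 to 30.1), endothelial-like cells 22.4% (21.2 to 23.6) and T cell-like cells 10.4% (9.54 to 11.3) of 4543 cells. The mitochondrial limit sets the order of these shares, since with no limit B cell-like cells were 18.504% and endothelial-like cells 38.1%, and with a limit of 10% endothelial-like cells were 13.6%. Red blood cell precursors led in the library labelled P180, where erythroid-like cells made up 78.1% (77.2 to 79.0) and neutrophil-like cells and their precursors 12.1% (11.4 to 12.8) of 8847 cells. Erythroid-like cells were 1.80% (1.44 to 2.24) with the E18.5 label, and 0.638% when both libraries were clustered together. The minimum of 200 genes left out 1352 barcodes of that library rich in haemoglobin; without it, an alternative chosen after seeing the data, such barcodes were 14.3% with the E18.5 label and 56.6% with the P180 label. Blood formation is a main function of the fetal liver and mature B, T and plasma cells are features of adult tissue, so these directions run against the stage labels.

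Further classes with the E18.5 label were neutrophil-like (8.78%, 7.98 to 9.64), dendritic-like (6.25%, 5.56 to 6.99), macrophage-like (4.31%, 3.74 to 4.95), NK cell-like (3.96%, 3.41 to 4.57), monocyte-like (3.83%, 3.29 to 4.43) and cholangiocyte-like (3.32%, 2.82 to 3.89) cells. Plasma cell-like cells were 2.14% (1.73 to 2.60) and mesenchymal-like cells, which include stellate cells and fibroblasts, 2.05% (1.66 to 2.5). With the P180 label, monocyte-like cells were 3.21% (2.85 to 3.60), B cell-like 2.27% (1.97 to 2.60), endothelial-like 1.24% (1.02 to 1.5), dendritic-like 0.780% (0.607 to 0.986) and mesenchymal-like 0.497% (0.362 to 0.667). No cluster of these 8847 cells took the name of T, NK, plasma cells, macrophages or cholangiocytes, which does not exclude single cells of these types; clustering of both libraries together placed 5 T cell-like, 11 NK cell-like and 8 cholangiocyte-like cells there. Clusters without a name made up 2.0% and 1.81%, with the E18.5 and the P180 label. A cluster of 15 cells labelled E18.5 stays unnamed with 4 markers each of hepatocytes (Alb, Ambp, Apoa2, Ttr) and of cholangiocytes. A cluster of hepatocyte-like cells was found in neither library under these filters, so the comparison of hepatocytes and their zonation between the stages could not be made. Dissociation and the filters can both set such shares.

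**Figure D2:**
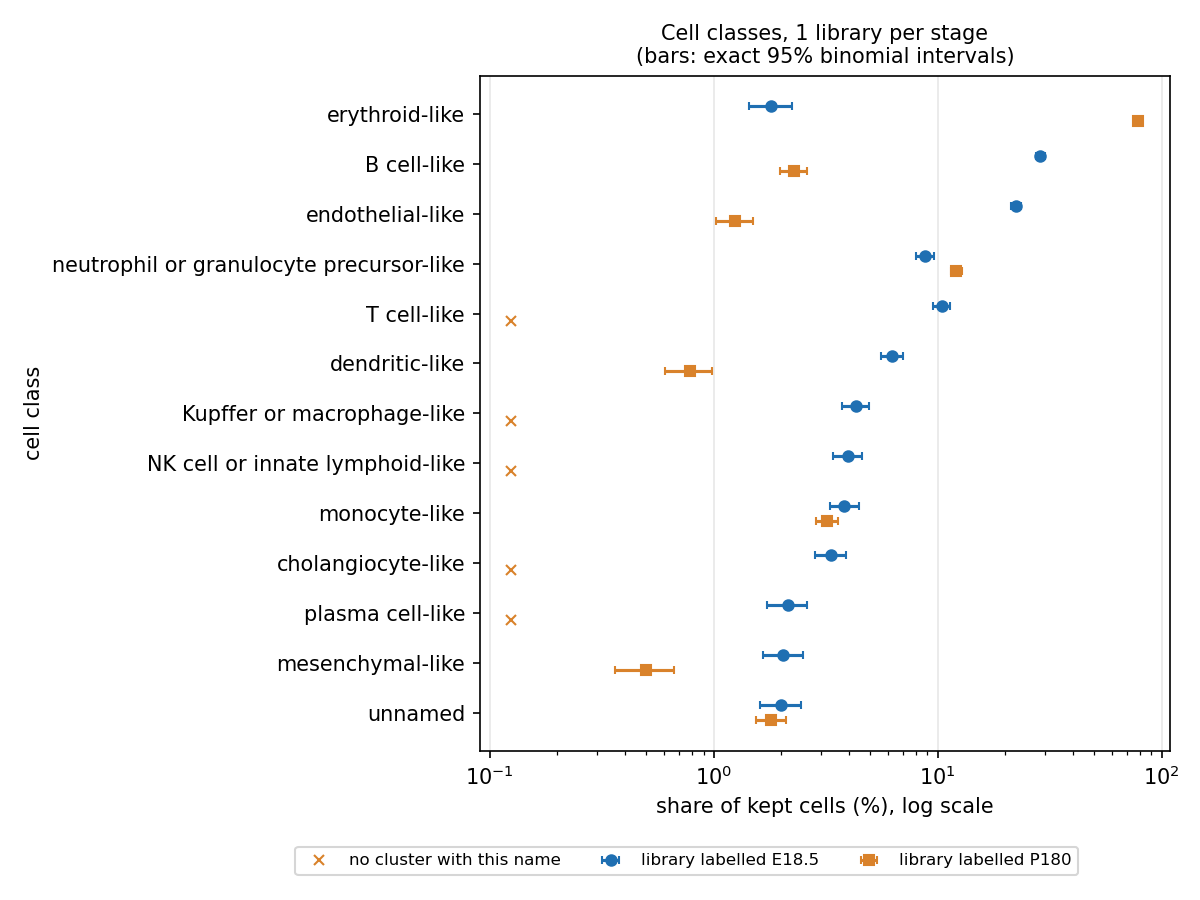
Share of kept cells in each cell class, in percent on a log axis, for the libraries labelled E18.5 (4543 cells) and P180 (8847 cells); points are shares, bars exact binomial 95% intervals, and crosses mark classes with no cluster of that name. B cell-like cells are at 28.8% and 2.27%, and erythroid-like cells at 1.80% and 78.1%, with the E18.5 and the P180 label.

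Endothelial-like cells (1016 with the E18.5 label, 110 with the P180 label) were compared as the class of liver tissue present in both libraries with enough cells. Under 3 alternatives (no doublets left out, Scrublet's own threshold, resolution 0.5) the cells labelled P180 joined a mesenchymal-like cluster, so this comparison rests on the clustering. Genes of fetal growth were far higher in the library labelled P180, against the stage labels. Of 9 measured genes of the fetal list, 7 were at least 2-fold higher there, 0 at least 2-fold lower and 2 between. Their median log2 ratio, labelled P180 over labelled E18.5 as in all ratios below, was 4.07, at percentile 100 of 10000 matched random lists; with members from 200 UMIs up it was 1.60, over 5 genes. H19, an imprinted non-coding RNA of embryonic tissues, stood at 24.4 and 409 CPM (16.8-fold, 13.2 to 21.4), and its neighbour Igf2, a fetal growth factor, at 5.33 and 279 CPM (log2 ratio 5.71, 5.05 to 6.44). Igf2bp3, an RNA-binding protein of fetal cells, stood at 1.52 and 94.5 CPM, the imprinted Peg3 at 4.57 and 176 CPM, and Mest at 125 and 923 CPM.

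These fetal transcripts were spread unevenly over the endothelial-like cells labelled P180. Mest was found in 81.8% of them and in 26.6% with the E18.5 label, and Igf2bp3 in 34 of 110 (30.9%) against 6 of 1016. H19 was found in 23 of the 110 cells (20.9%, 13.7 to 29.7) against 21 of 1016 (2.07%, 1.28 to 3.14). Igf2 was found in 10 cells (9.09%, 4.45 to 16.1) against 7 (0.689%). With the P180 label these cells held 255 H19 UMIs and 174 Igf2 UMIs, a spread that the intervals of the ratios leave out. As background in the same library, 0.478% of erythroid-like cells carried an H19 UMI and 0.0868% an Igf2 UMI, at median depths of 5219 UMIs against 3353.5 UMIs in endothelial-like cells. H19 (ENSMUSG00000000031) lies on mm10 chromosome 7 from 142575529 to 142578143 and Igf2 (ENSMUSG00000048583) from 142650766 to 142666816, both on the minus strand.

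Genes of cell division were likewise higher in endothelial-like cells labelled P180. Of 12 measured proliferation genes, 9 were at least 2-fold higher with the P180 label and 0 lower by that size (median 3.05, percentile 100; 0.81 over the 4 genes from 200 UMIs up). Mki67, a marker of dividing cells, stood at 0.762 CPM (3 UMIs) and 183 CPM (log2 ratio 7.91, 6.32 to 10.20), and Top2a, the topoisomerase of dividing cells, at 2.29 and 114 CPM. Cells with an Mki67 UMI were 3 of 1016 (0.295%) and 13 of 110 (11.8%, 6.45 to 19.4), and 72 of the 114 UMIs with the P180 label came from 1 cell. As background in that library, Mki67 stood at 421 CPM over all cells and was found in 59.4% of erythroid-like cells. The list's median level in endothelial-like cells was 0.493 of that over the library, and haemoglobin took 11.4% of UMIs in the 13 cells against 2.49% in the others, so transcripts of dividing erythroid-like cells are not excluded as the source. Within the list of endothelial proliferation and angiogenesis, 5 of 13 genes were at least 2-fold higher and 0 lower, yet the median was 0.29 (percentile 94.3). The 5 were Mki67, Top2a, Stmn1, Igf2 and H19, and receptors of vessel growth differed little, with Kdr at 856 and 849 CPM and Flt1 at 860 and 864 CPM.

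Genes of vessel identity were compared over the whole class, which under the E18.5 label includes an Rspo3- and Vwf-led cluster of 254 cells with no counterpart of its own under the P180 label. In the capillary and large vessel list, 6 of 12 genes were at least 2-fold lower with the P180 label, 1 was higher and 5 lay between (median -1.08, percentile 0). Ly6a, a surface protein of endothelial and blood stem cells, stood at 718 and 30.4 CPM (log2 ratio -4.56, -5.29 to -3.91), Esm1 at 75.2 and 3.20 CPM (2 UMIs; -4.55, -7.60 to -2.69) and Clu at 55.4 and 4.81 CPM (3 UMIs; -3.53, -5.82 to -1.96). Aplnr, the apelin receptor of growing vessels, was the member on the higher side, at 2.03 and 99.3 CPM (48.9-fold). Within the Stab2-led clusters alone, a comparison chosen after seeing the data, the median of this list was -0.38, and that of the liver sinusoid list -0.72, so the order of these lists is reversed there. In the whole class liver sinusoid genes differed less, with 1 of 18 at least 2-fold higher, 3 lower and 14 between (median -0.18, percentile 13.5); scaled by the median of ratios, 5 were lower and the median was -0.31. Lyve1, a hyaluronan receptor of sinusoids, stood at 177 and 681 CPM (3.84-fold, 3.40 to 4.34), while Fcgr2b, an antibody receptor, stood at 518 and 135 CPM. Rspo3 and Wnt9b, Wnt pathway signals made by vessels near the central vein, stood at 1991 and 848 CPM and at 65.5 and 32.0 CPM.

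**Figure D3:**
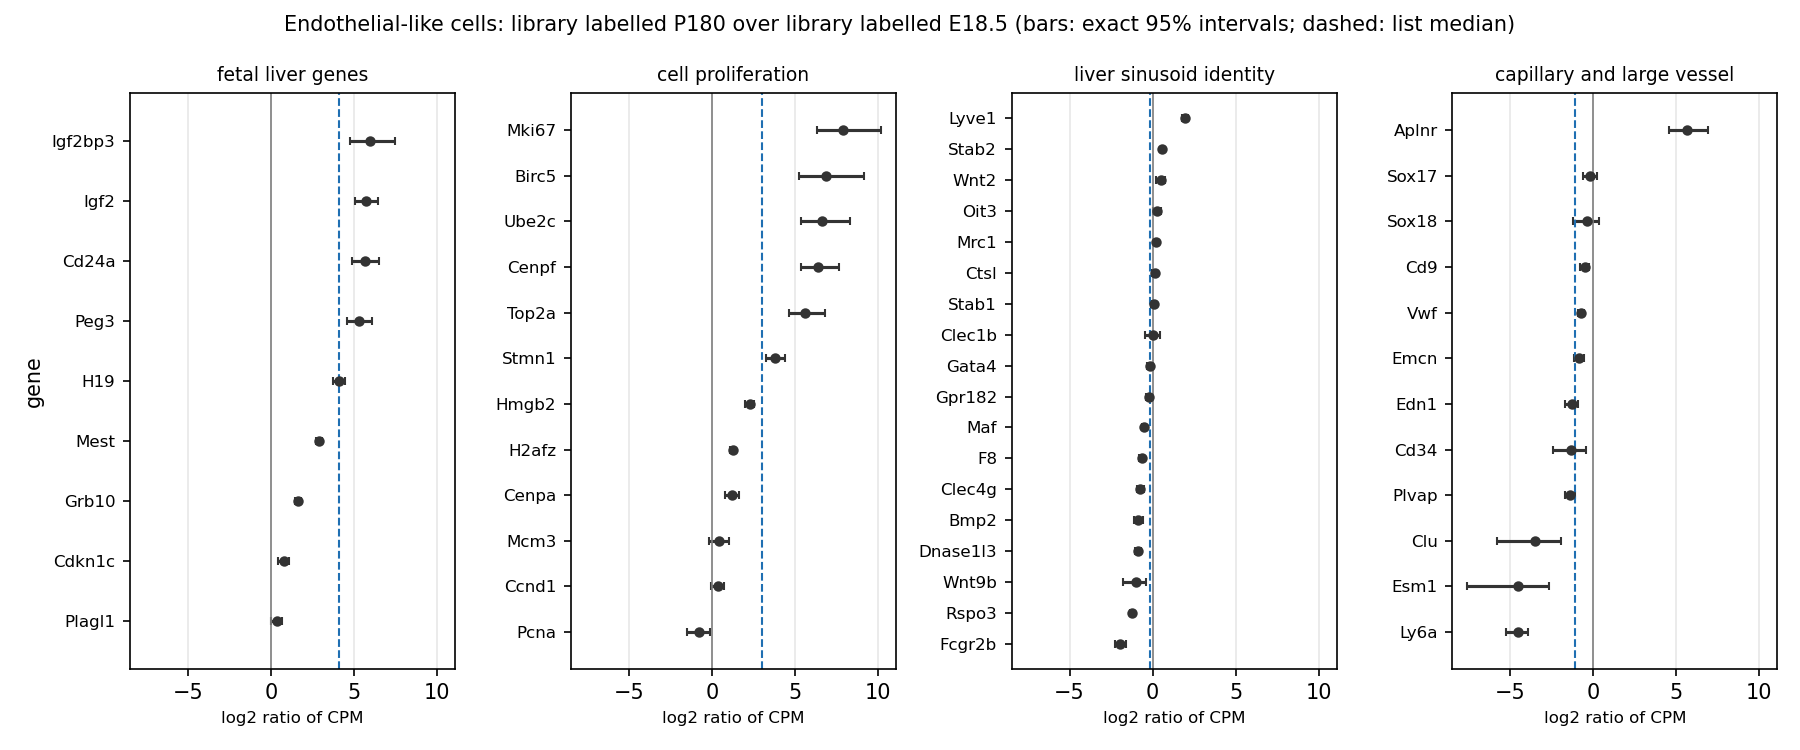
Log2 ratio of CPM, library labelled P180 over library labelled E18.5, for the measured members of gene lists in endothelial-like cells; each point is a gene, each bar its exact 95% interval and each dashed line the list's median. The fetal list has a median of 4.07 and the proliferation list 3.05, while the capillary and large vessel list lies at -1.08 and the sinusoid list at -0.18.

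Extreme ratios were taken among genes with at least 200 UMIs that are no marker of another class and at least as high in the class as in its whole library, here and in the classes below. By this rule the 4 lowest ratios in endothelial-like cells were those of Xist, at 1573 CPM and 0 (at least 327-fold lower with the P180 label), of Fmo2, a monooxygenase, at 181 and 1.60 CPM (log2 ratio -6.82), of Galnt15 at 112 and 1.60 CPM (-6.12) and of Csmd1 at 187 and 3.20 CPM (-5.87). Both Fmo2 and Galnt15 rest on 1 UMI, and Csmd1 on 2, in the library labelled P180; their intervals were -12.13 to -4.34, -11.43 to -3.63 and -8.91 to -4.01. By the same rule the highest were those of H19, a member of the fetal list (4.07), of Ppp1r9a, a protein of the actin skeleton, at 30.2 and 498 CPM (4.04), of Adamtsl1 at 63.0 and 820 CPM (3.70) and of Trerf1 at 43.9 and 327 CPM (2.90). Different clusters hold the class in each library, since a Stab2-led cluster of 596 cells, the Rspo3- and Vwf-led cluster and a Mecom-led cluster of 166 make it up under the E18.5 label and a single cluster led by Fabp4, Ptprb and Stab2 under the P180 label.

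Erythroid-like cells (82 and 6909) shared their main product and differed in cell division. The adult globins were at similar levels, with the beta chain gene Hbb-bs at 281662 CPM with the E18.5 label and 319487 CPM with the P180 label, and the alpha chain gene Hba-a1 at 138743 and 150094 CPM. Of 30 measured proliferation genes, 30 were at least 2-fold higher with the P180 label (median 3.22, percentile 100), among them Rrm2, which makes the building blocks of DNA, at 4.74 CPM (2 UMIs) and 277 CPM (log2 ratio 5.87, 4.02 to 8.92). In the globin list, 1 of 8 genes was at least 2-fold higher, 1 lower and 6 between (median 0.23, percentile 37.1); the median of all genes in this class was -0.89, and scaled by the median of ratios 6 were higher, 1 lower, and the list's median 1.12. Slc25a37, the importer of iron into mitochondria, stood at 424 and 2034 CPM (2.26, 2.05 to 2.48), and Alas2, the first enzyme of haem synthesis in these cells, at 960 and 1495 CPM (0.64, 0.50 to 0.78). Bpgm, which tunes oxygen release, stood at 737 and 977 CPM (0.41, 0.24 to 0.57). Bcl11a, a repressor of fetal globin genes that B cells express too, stood at 85.3 and 9.45 CPM (-3.17, -3.67 to -2.64).

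Embryonic globins were seen under the P180 label alone, with 105 UMIs of Hbb-y (2.44 CPM, 1.99 to 2.95) and 59 UMIs of Hbb-bh1 (1.37 CPM, 1.04 to 1.77) in erythroid-like cells. With the E18.5 label both counts were 0, which allows up to 8.74 CPM in so few UMIs, so a difference was not detectable at this depth. By the rule above, the highest ratios were those of Rrm2, of Syt14 at 4.74 CPM (2 UMIs) and 440 CPM (6.54, 4.68 to 9.58), of the red cell adhesion protein Icam4 at 2.37 CPM (1 UMI) and 158 CPM (6.06, 3.58 to 11.36) and of the cell cycle gene Cdca3 at 2.37 CPM (1 UMI) and 124 CPM (5.71, 3.23 to 11.01). By the same rule the lowest were those of genes that include some expressed in B cells, namely Bank1 at 759 and 0.116 CPM (-12.67), Bach2 at 841 and 0.859 CPM (-9.94) and Prkcb at 427 and 5.5 CPM (-6.28), and with them Dipk1a at 116 and 6.62 CPM (-4.13). The erythroid-like cluster labelled E18.5 carries B cell transcripts beside haemoglobin, with Ighm, Ebf1 and Bank1 among its leading genes. Without cells carrying a B cell marker UMI, an alternative chosen after seeing the data, 49 and 6720 cells remained and the globin median was -0.03.

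B cell-like cells (1307 and 201) differed in genes of B cell development. The surrogate light chain genes Vpreb1 and Igll1, used by B cell precursors, stood at 0.154 CPM (1 UMI) and 290 CPM (log2 ratio 10.88, 8.40 to 16.19), and at 0 and 353 CPM (at least 765-fold higher). A UMI of Vpreb1, Igll1 or the recombinase gene Rag1 was found in 1 of 1307 cells (0.0765%) with the E18.5 label and in 73 of 201 cells (36.3%, 29.7 to 43.4) with the P180 label; as background, 0.217% of erythroid-like cells labelled P180 carried a Vpreb1 UMI. Ighd, the heavy chain of mature B cells, was seen in 76.7% of B cell-like cells with the E18.5 label and 29.9% with the P180 label, at 575 and 38.6 CPM. All 30 measured proliferation genes were at least 2-fold higher with the P180 label (median 5.51, percentile 100), with the cyclin gene Ccna2 at 0.307 CPM (2 UMIs) and 152 CPM (8.95, 7.09 to 12). All 3 measured fetal genes were higher too (median 4.77, percentile 99.8), with Lin28b, a regulator of fetal lymphocyte development, at 0.154 CPM (1 UMI) and 37.0 CPM (7.91, 5.39 to 13.23).

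Gfra1, a receptor for glial growth factors, stood at 0.154 CPM (1 UMI) and 162 CPM in B cell-like cells (10.04, 7.55 to 15.35). By the rule above, the lowest ratios were those of Xist, at 1618 CPM and 0 (at least 1285-fold lower), of the mineralocorticoid receptor gene Nr3c2, at 142 and 0.420 CPM (1 UMI; -8.40, -13.70 to -5.92), of Trim7, at 98.7 and 0.420 CPM (1 UMI; -7.88, -13.18 to -5.39), and of Vmn2r96, a vomeronasal receptor gene, at 282 CPM and 0 (at least 224-fold lower). Dntt, which adds bases at antibody gene joins, was found in 2 of the 73 precursor-like cells labelled P180 (2.74%, 0.334 to 9.55).

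Monocyte-like cells (174 and 284) differed in genes of cell division and of granules. Mki67 was found in 2.30% and 68.7% of them, at median depths of 8040 and 24088 UMIs. The ratios here do not separate cells of different maturity under 1 class name from changes within 1 cell type. Of 31 measured proliferation genes, 30 were at least 2-fold higher with the P180 label (median 5.62, percentile 100), and 7 genes enter at a bound from a count of 0. Those 7 are at least 2-fold higher by construction. By the rule above, which leaves out markers of neutrophils, the highest ratios were those of genes of cell division. Top2a stood at 0.697 CPM (1 UMI) and 235 CPM (log2 ratio 8.39, 5.91 to 13.70), Cdca8 at 0.697 CPM (1 UMI) and 182 CPM (8.03, 5.54 to 13.33), Ccnb2 at 0.697 CPM (1 UMI) and 174 CPM (7.97, 5.49 to 13.27) and Pclaf, a partner of the replication clamp, at 0 and 506 CPM (at least 242-fold higher). Among those markers, the granule genes Elane and Mpo were higher still, at 0.697 CPM (1 UMI) and 738 CPM (log2 ratio 10.05) and at 0.697 CPM (1 UMI) and 1055 CPM (10.56). Higher with the E18.5 label were Cxcl9, an interferon-induced chemokine, at 635 and 0.823 CPM (-9.59), Stxbp6 at 289 and 10.7 CPM (-4.75), Tppp3 at 139 and 5.21 CPM (-4.74) and Gngt2 at 454 and 20.8 CPM (-4.44).

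All 12 measured fetal genes were at least 2-fold higher in monocyte-like cells labelled P180 (median 2.76, percentile 99.99). Of these, 9 had a count of 0 with the E18.5 label and enter at their lower bound. For these 9 the minimum of UMIs makes the ratio at least 2-fold by construction, so the count of 12 says little. In 15 of the 284 cells an Alb UMI was found, 894 such UMIs in all. With these cells left out, as chosen after seeing the data, the median was 2.37 over 5 genes. Thus only 5 of the 12 genes reached the minimum of UMIs without those few cells.

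Dendritic-like cells (284 and 69) also differed in cell division, but different clusters hold the class in each library. Under the E18.5 label a cluster of 146 cells has Xcr1 and Clec9a among its markers and one of 138 cells Cd209a, while the single cluster under the P180 label has none of these, so the ratios here do not separate dendritic subtypes from changes within 1 subtype. In the whole class 22 of 26 measured proliferation genes were at least 2-fold higher with the P180 label (median 3.21, percentile 100). Cks1b, a partner of the cell cycle kinases, stood at 27.5 and 180 CPM (log2 ratio 2.71, 2.39 to 3.04) and H2afx, a histone of DNA repair, at 36.8 and 240 CPM (2.71, 2.43 to 2.99). Igf2bp3 stood at 0.757 CPM (3 UMIs) and 149 CPM (7.62, 6.05 to 9.91) and Ifi202b, an interferon-induced gene, at 30.5 and 169 CPM (2.47, 2.15 to 2.79). Of the fetal list 2 genes were measured in this class, too few for a median. Higher with the E18.5 label were the chemokine gene Ccl22 at 67.1 and 0.611 CPM (1 UMI; -6.78, -12.09 to -4.29) and the actin bundler gene Fscn1 at 52.7 and 0.611 CPM (1 UMI; -6.43, -11.74 to -3.94). S100a4 stood at 432 and 1.83 CPM (3 UMIs; -7.88, -10.16 to -6.33), and Adgrl3 at 170 CPM and 0 (at least 92.5-fold lower).

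Neutrophil-like cells (399 and 1070) differed in levels of genes used to name them. Camp, a gene of late granules, stood at 5115 and 32385 CPM and was found in 7.77% and 97.48% of cells, and Ngp, of the same granules, at 4302 and 24569 CPM in 9.52% and 94.9%. The shares labelled P180 say little by themselves, since Camp was found in 56.4% of erythroid-like and 81.3% of monocyte-like cells there, at 138 and 80.9 CPM, and Ngp in 39.2% and 59.9%. With the E18.5 label 20 of the 399 cells lay in a cluster with Camp and Ngp among its markers. Elane, Mpo and Prtn3, early granule genes, led a cluster of 139 cells labelled P180. Il1b, the inflammatory cytokine of mature neutrophils, stood at 4522 CPM with the E18.5 label and 43.6 CPM with the P180 label (log2 ratio -6.70). Retnlg and Cxcr2, genes of mature cells, were found in most cells of both libraries (85.0% and 73.5%, 83.7% and 73.5%). They stood at 5820 and 1339 CPM (-2.12) and at 671 and 91.3 CPM (-2.88). The Retnlg ratio depends on the scaling. As the mean of CPM per cell, its lowest value in the 5 compared classes other than erythroid-like was -0.84. Of 30 measured proliferation genes, 29 were at least 2-fold higher with the P180 label (median 3.12, percentile 100), while 1 of 3 fetal genes was (median 0.34, percentile 46.4).

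The stefin A genes, protease inhibitors of neutrophil precursors, had the highest ratios in neutrophil-like cells by the rule above. Csta2 stood at 1.47 CPM (2 UMIs) and 2941 CPM (log2 ratio 10.97, 9.12 to 14.01), Stfa3 at 13.9 and 10305 CPM (9.53), Stfa1 at 52.1 and 37257 CPM (9.48) and Cstdc5 at 48.5 and 32209.8 CPM (9.38). These paralogs are near-identical, so their single values are uncertain. By the same rule ratios were lowest for Vmn2r96, at 189 CPM and 0 (at least 1323-fold lower), Wfdc17 at 1938 and 6.04 CPM (-8.33), Prr5l at 200 and 1.57 CPM (-6.99) and the prostaglandin synthase gene Ptgs2 at 262 and 2.09 CPM (-6.97). As background, Stfa1 was found in 53.8% of erythroid-like and 53.7% of B cell-like cells labelled P180, and in 0.0765% of B cell-like cells labelled E18.5.

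Across the 6 classes compared, every median of the proliferation list lay at percentile 100, from 3.05 in endothelial-like to 5.62 in monocyte-like cells, all higher with the P180 label; from 200 UMIs up it was 0.81 in endothelial-like (4 genes) and 1.79 in dendritic-like cells (7 genes). Within the library labelled P180, the list's median level in a class was 0.493 (endothelial-like) to 1.31 (monocyte-like) of that over all cells. Haemoglobin, which free RNA of the whole library would bring along, took 3.08% of UMIs in B cell-like, 1.62% in neutrophil-like, 1.46% in monocyte-like and 0.419% in dendritic-like cells, against 34.9% over the library, too little for such RNA to be the whole source in these classes. Doublets with other dividing cells were not tested. The medians do not separate a different makeup of a class in each library from changes within 1 cell type. Regulators of cytokinesis and ploidy, fixed because the donor cells are tetraploid, had medians of 0.19 to 4.30 (percentiles 71.4 to 100), the lowest in endothelial-like cells, where 1 of 4 measured genes was at least 2-fold higher. Scaled by the median of ratios, 13 in place of 11 of 15 were higher in erythroid-like cells. Genes of the centrosome and spindle checkpoint had medians of 0.27 to 1.37 (percentiles 87.1 to 99.4). Their count at least 2-fold higher was 0 of 8 in endothelial-like, 1 of 7 in dendritic-like, 7 of 14 in B cell-like, 9 of 15 in erythroid-like, 10 of 15 in monocyte-like and 11 of 16 in neutrophil-like cells. Scaled by the median of ratios it was 0 in dendritic-like, 13 in erythroid-like and 13 in neutrophil-like cells, and in B cell-like cells 2 became at least 2-fold lower. Targets of p53, the tumour suppressor that responds to DNA damage, had medians of -0.45 to 0.18 (percentiles 2.33 to 68.4), of which 5 of 6 were below 0. Of 16 targets 0 were at least 2-fold higher and 2 lower in dendritic-like cells, of 17 there were 1 and 2 in endothelial-like, of 20 there were 4 and 6 in monocyte-like, and of 20 there were 6 and 7 in neutrophil-like cells. In B cell-like cells 4 of 19 were higher and 5 lower, against 2 and 8 scaled by the median of ratios, and in erythroid-like cells 4 of 14 were higher and 4 lower, against 7 and 2.

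Genes that respond to dissociation stress and mitochondrial transcripts, signs of cell handling and RNA quality, differed between the libraries too. Stress medians were between -2.01 and -0.45 (percentiles 0 to 0.46), higher with the E18.5 label in each class. The immediate early gene Fos stood at 1638 and 101 CPM in B cell-like cells (log2 ratio -4.02), with the E18.5 and the P180 label, Atf3 at 1438 and 22.1 CPM in neutrophil-like cells (-6.02), and the heat shock gene Hspa1b at 318 and 38.5 CPM in endothelial-like cells (-3.05). Scaled by the median of ratios, the stress genes at least 2-fold lower were 7 in place of 4 of 18 in endothelial-like, 6 in place of 3 of 18 in dendritic-like and 8 in place of 12 of 17 in erythroid-like cells. Medians of mitochondrially encoded genes were between -4.98 and -0.85, also higher with the E18.5 label. Haemoglobin and other erythroid genes, which classes other than erythroid-like should lack, had medians of 0.95 to 5.0, higher with the P180 label in all 6; in erythroid-like cells 7 of 12 were at least 2-fold higher, and 11 scaled by the median of ratios. Genes of plasma proteins, made by hepatocytes, lay the other way in B cell-like and endothelial-like cells. In B cell-like cells 14 of 14 were at least 2-fold lower with the P180 label, 5 of them at their bound (median -3.48, percentile 0.01). In endothelial-like cells 6 of 7 were lower (-1.39, percentile 1.66). In monocyte-like cells 2 of 16 were lower and 8 higher (0.99), and in neutrophil-like cells 2 of 5 were lower and 1 higher. Of the 284 monocyte-like cells labelled P180, 15 carried an Alb UMI, and this list was not recomputed without them. An Alb UMI was found in 30.5% (erythroid-like) to 38.4% (dendritic-like) of cells of the 6 classes labelled E18.5, and in 0% (B cell-like) to 5.45% (endothelial-like) of those labelled P180. With total scaling, the median log2 ratio of all genes was 0.28 in B cell-like, 0.12 in dendritic-like, 0.13 in endothelial-like, 0.20 in monocyte-like and -0.16 in neutrophil-like cells, and list medians are to be read relative to it.

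The sex-linked transcripts separated the libraries. Xist, the RNA that silences an X chromosome in female cells, had 37345 UMIs with the E18.5 label and 8 with the P180 label. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 32 UMIs with the E18.5 label and 10292 with the P180 label. By these transcripts the libraries differ in sex as well as in stage label, so no ratio between them separates stage from sex. The low ratios of Xist in endothelial-like and B cell-like cells belong to this difference. With cells thinned to 1000 UMIs, which left out 46 and 490 shallower cells, Xist was found in 62.6% (61.2 to 64.0) of cells labelled E18.5 and 0.0120% of cells labelled P180, and a Y-linked UMI in 0.111% (0.0361 to 0.259) and 11.5% (10.8 to 12.2). Unthinned shares were 85.5% and 0.0904% for Xist, and 0.704% and 45.4% for the Y-linked genes. By class, Xist ran from 9.80% in neutrophil-like and 28.0% in erythroid-like to 81.5% in cholangiocyte-like cells labelled E18.5, and Y-linked UMIs from 10.0% in neutrophil-like to 34.9% in endothelial-like cells labelled P180. The comparison was made because host and donor cells of opposite sex would be told apart by these genes. Xist (ENSMUSG00000086503) lies on the minus strand of the mm10 X chromosome from 103460366 to 103483254. On the Y chromosome Kdm5d spans 897788 to 956786, Eif2s3y 1010543 to 1028847, Uty 1096861 to 1245759 and Ddx3y 1260771 to 1286629.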

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

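Of the tests in this part, both tests of the barcodes with a high mitochondrial share were chosen only after the result was seen.

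In the library labelled E18.5, 4020 of 9871 barcodes (40.7%, 39.8 to 41.7) took at least 25% of their UMIs from mitochondrially encoded genes and entered no comparison, against 176 of 9771 (1.80%) in the library labelled P180. They are given because the comparisons leave them out and their number is above 0, which any such group would meet, so the share is a description and not a test. Neither explanation is argued against by the bounds of its own test. Damaged cells that lost their cytoplasmic RNA may account for it, since the median of 236 genes in these barcodes was 0.138 of the median of 1706 in the others. The test of hepatocytes, rich in mitochondria, came out undecided. Their markers took 3.23 times the share of other UMIs (0.304% against 0.0940%, with Alb at 1340 and 438 CPM), between the bounds of 2 and 5 set for this test. Yet 27 of the 4020 barcodes held hepatocyte markers as at least 5% of other UMIs. This argues against hepatocytes as most of these barcodes and leaves open a small part. A difference of age or of dissociation between the libraries was not tested.

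Barcodes with haemoglobin as at least 50% of their UMIs and under 200 genes numbered 1352 (13.7%, 13 to 14.4) with the E18.5 label and 13 with the P180 label. They had medians of 86 genes and 2627 UMIs with the E18.5 label, and stand out because the minimum of 200 genes leaves them out of every comparison. With no minimum of genes, an alternative chosen after seeing the data, haemoglobin-rich barcodes of any kind were 1413 (14.3%) and 5535 (56.6%, 55.7 to 57.6). The larger share thus remained with the P180 label.

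Hepatocyte markers made up at least 5% of non-mitochondrial UMIs in 27 barcodes (0.274%, 0.180 to 0.398) of the library labelled E18.5, all of them at or above the mitochondrial limit and so outside every comparison. Their medians were 103 genes and 606 UMIs. In the library labelled P180 there were 3 such barcodes, 2 of which passed the filters. No explanation was tested for this or for the haemoglobin-rich barcodes.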

How the results depend on the processing

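Alternatives on the Stab2-led clusters, on erythroid-like cells without B cell markers and on monocyte-like cells without Alb were chosen only after the data were seen. No paired analysis was possible because each stage has 1 library. The tdTomato alternatives were not run since the gene table lacks the transgene, nor those on hepatocytes and zonation, since no cluster of hepatocyte-like cells was found; joint clustering alone gave one, with 18 and 4 cells, and also placed 5 T cell-like, 11 NK cell-like and 8 cholangiocyte-like cells under the P180 label.

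Of 64 shares in the classes central to the comparison of cell makeup, 45 stayed within the interval of the reported share and 19 moved, as did 41 of 160 further shares. With a mitochondrial limit of 10%, the library labelled E18.5 kept 2760 cells, with 13.6% endothelial-like and 4.82% neutrophil-like, and endothelial-like cells labelled P180 were 0.829%. Fewer cells pass such a limit by construction. With no limit, shares with the E18.5 label were 18.504% B cell-like, 38.1% endothelial-like and 1.18% erythroid-like, and endothelial-like cells labelled P180 were 1.99%; Hhex was 109 CPM in endothelial-like and 34.5 CPM in neutrophil-like cells labelled E18.5, and 84.6 CPM in monocyte-like cells labelled P180. From 1000 UMIs up, shares with the P180 label were 76.8% erythroid-like and 12.8% neutrophil-like. With no doublets left out, and with Scrublet's threshold, erythroid-like cells labelled P180 were 71.3% and 71.3%, and neutrophil-like cells labelled E18.5 10.6% and 10.5%. Under both, and at resolution 0.5, endothelial-like cells labelled P180 were 0%, because they joined a cluster named mesenchymal-like of 222, 222 and 154 cells with Ptprb among its leading genes. Resolution 0.5 gave 10.5% neutrophil-like cells labelled E18.5, and joint clustering 0.638% and 79.6% erythroid-like cells. Apart from the smaller number of cells and this merger, the cause was not tested. Without thinning, the shares were 85.5% and 0.0904% for Xist and 0.704% and 45.4% for Y-linked genes, higher because unthinned cells hold more UMIs.

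No list median called by its place among random lists reversed, and 12 of 35 medians of lists fixed for their class, or answering the comparison, moved. These medians were taken under the scalings, list minimums and later-chosen subsets of cells, all on the main clustering. They were not recomputed under the other mitochondrial limits, UMI minimum, doublet settings, resolutions or joint clustering. Across the settings recomputed, the proliferation list kept its sign in 39 of 39 medians (0.81 to 5.76). The lowest was that of endothelial-like cells over 4 genes from 200 UMIs up. The stress list kept its sign in 36 of 36 (-2.36 to -0.45) and the fetal list in 26 of 29 (-0.61 to 5.27). Capillaries and large vessels kept theirs in 7 of 7 (-1.30 to -0.38) and sinusoids in 7 of 7 (-0.72 to -0.18). The globin list kept its sign in 6 of 7, with 1.12 scaled by the median of ratios and 0.16 without haemoglobin and mitochondrial genes. It stood at 0.26 without the 50 most abundant genes, 0.082 per cell and -0.033 without B cell markers. Endothelial proliferation and angiogenesis kept it in 6 of 7 (-0.0020 from 200 UMIs up). Sinusoids stood at -0.42 per cell and -0.72 in Stab2-led clusters, capillaries at -1.30 from 200 UMIs up and -0.38 in Stab2-led clusters, with the fetal list changing sign in neutrophil-like (-0.28 per cell, -0.61 from 10 UMIs) and erythroid-like cells (-0.48 from 10 UMIs) and standing in endothelial-like cells at 5.27 from 10 UMIs and 1.60 from 200 UMIs up. A higher minimum tests fewer genes, and otherwise the cause was not tested. Depth limits the rare transcripts, such as Hbb-y in 82 erythroid-like cells labelled E18.5.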

Other observations

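Of the tests in this part, those of the other sex's transcripts by level, over a whole library and within classes, were chosen only after the result was seen, as were the further genes named here.

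Mesenchymal-like cells were too few to compare (93 with the E18.5 label, 44 with the P180 label). In the 44 cells H19 stood at 1245 CPM (found in 84.1%), Igf2 at 411 CPM (77.3%) and Dlk1, a fetal inhibitor of Notch, at 1259 CPM (88.6%), with 0 UMIs of each in the 93 cells. Over all kept cells, Igha, the heavy chain of secreted antibody, had 105482 UMIs with the E18.5 label and 1 with the P180 label, Hbb-y 0 and 106 and Hbb-bh1 0 and 59 (with 82 and 6909 erythroid-like cells), and Lin28b 3 and 771.

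H2-K1, H2-D1, B2m and Nlrc5, picked genes of antigen presentation on class I for which no list was fixed, were lower with the P180 label in all 5 compared classes other than erythroid-like cells, under every scaling of totals and as the mean of CPM per cell. Log2 ratios ran from -3.38 to -0.94 for H2-K1, -2.94 to -0.62 for H2-D1, -2.43 to -1.04 for B2m and -6.16 to -1.65 for Nlrc5, the activator of these genes. Cd274, a ligand that restrains T cells, ran from -6.46 to -1.34, where 1 of the 5 is a bound from a count of 0. As means per cell the ratio nearest to 0 was that of H2-D1, at -0.22. The fixed list of antigen presentation and inflammation, which holds class II genes and markers of dendritic cells, had medians of -4.75 to -0.37 in these 5 classes (percentiles 0 to 1.32), with 6 to 15 members measured; erythroid-like cells are left aside, since those labelled E18.5 carry B cell transcripts.

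Genes and cell classes tied to age lie on the side opposite to the stage labels in both libraries. The tables argue against blood formation in an adult liver with the labels right, since endothelial-like cells labelled P180 would then not carry fetal genes above those of a fetus, while the median log2 ratio was 4.07 (1.60 with members from 200 UMIs up). The tables also argue against free RNA with the makeup of the whole library, since the fetal list's 9 members stood at a median of 33.8 times their whole-library level in the endothelial-like cells labelled P180 (0.154 to 67.7). These members were chosen by their UMIs in this class, which raises that median. Doublets, or cells of another class within the cluster, were not tested. An exchange of labels between the libraries may be the source, as it needs a median above 1. It also needs partners out of place in both libraries. These are plasma cells and mature lymphocytes under the E18.5 label, and precursors of red blood cells and B cells under the P180 label. Those partners raised the question, so they are no separate test of it. The fetal list was fixed for hepatocytes and applied to endothelial-like cells after the clusters had been seen. An exchange remains a hypothesis, since nothing in the labels can check it. Under 3 alternatives no separate endothelial-like cluster labelled P180 exists to be compared. A difference between these chimaeric animals and other mice of the same ages was not tested.

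Xist marks the cells labelled E18.5 and Y-linked genes those labelled P180. Over a whole library, the tables argue against more than a small part of cells of the other sex, since Y-linked levels labelled E18.5 were 0.883% (0.604 to 1.25) of those labelled P180, and Xist labelled P180 was 0.00754% of that labelled E18.5. Within the 6 compared classes labelled P180 they also argue against it, since Xist was at most 0.0456% of its level labelled E18.5, with upper limits of up to 0.376%, and within those labelled E18.5 Y-linked levels had upper limits of 0.427% in endothelial-like, 1.14% in B cell-like and 1.66% in dendritic-like cells. A mix stays open in monocyte-like (up to 2.71%), neutrophil-like (2.16%, 0.446 to 6.31) and erythroid-like cells labelled E18.5 (up to 8.67%), in classes named in only 1 library, and wherever host and donor cells share a sex. The share of thinned cells with the other sex's transcripts, at most 0.503% (neutrophil-like, labelled E18.5), does not settle this, since a Y-linked UMI is found in 10.0% of neutrophil-like cells labelled P180.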
